A study of Mus musculus with 8 samples.

How the data were processed

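RNA of single nuclei was measured in mouse liver, in 8 libraries. Per the labels' protocols, single lobes were snap frozen, nuclei were freed by douncing and purified on an Optiprep density gradient, and libraries were made with the Parse Evercode fixation and whole-transcriptome kits. Tables of exactly 10000 barcodes of 12 bases are not the usual form for these kits, so what a barcode stands for is uncertain. The submitters' processing notes name Seurat and the mouse build mm10, with no version or role for either. Each deposited table holds whole-number counts of 1 library, with genes in lines and 10000 barcodes of 12 bases in columns. The labels do not say whether these counts are of molecules or of reads, nor which barcodes hold nuclei, and no line of any table counts tdTomato or a human YAP1 transgene. Symbols were used as the files give them: 36879 occur in at least 1 table and 14932 in all 8, and 95.0% have a position in the GENCODE annotation of the mm10 build.

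The libraries were grouped as the labels name them into controls (tdTomato control and YAP no-dox control), YAP (4 days, 1 week and 2 weeks) and LATS (the same 3 times). The labels give no genotype beyond these words and no number of animals per library. A single time point is therefore 1 library without a replicate, and its values carry exact intervals but no test. The 3 arms were tested with libraries as the units, so the residual spread holds time, animal and library together.

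Barcodes with at least 200 genes and at most 20% of counts from mitochondrial genes were kept. By the plan, the mitochondrial limit was to be dropped if it removed over 50% of the barcodes of any library. It removed 24.7% to 41.8% of barcodes with at least 200 genes and was applied on that reading, which was chosen after the tables were seen. Over all listed barcodes it would remove over 50% in 5 libraries, up to 61.6%, and the plan would then have dropped it. Because 4046 of 62600 distinct barcodes occurred in more than 1 library, a shared barcode was kept only in the library where its count was at least 2 times that in any other, and a barcode was removed if another that differed at 1 base had at least 10 times its count. These 2 rules on barcodes were also chosen after the tables were seen. All limits together left 14549 barcodes. Scrublet, run with an expected rate of 0.06, marked 60 of them (0.412%), too few to count as working, so doublets largely remain among the 14489 barcodes used. Kept barcodes are called nuclei below. They numbered 1541 and 1613 in the tdTomato and no-dox controls, 679, 2326 and 1010 in YAP at 4 days, 1 week and 2 weeks, and 1611, 3202 and 2567 in LATS, before doublets were removed. Their median depths were 2070, 1704, 1687, 1007, 2575, 1550, 1659 and 1755 counts in the same order.

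Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes (chosen with the library as batch) and 30 principal components gave a 15-neighbour graph, clustered with the Leiden method at resolution 1 (Python 3.11.15, scanpy 1.11.5 with its igraph implementation). Of 13 clusters, 10 were named hepatocyte-like, 1 macrophage-like (a class defined for macrophage and monocyte markers) and 1 endothelial-like, from 15 marker lists. A cluster took the name of another list if at least 3 of that list's markers, and more than of the hepatocyte list, were among its 10 leading genes, and stayed unnamed if more but fewer than 3 were. Otherwise it was hepatocyte-like if at least 3 hepatocyte markers were detected in 50% of its nuclei, unless it was shallow without a hepatocyte marker among the 10. This way of naming was set after the tables were seen. The remaining cluster of 901 nuclei, of which 872 came from the YAP 2-week library, stayed unnamed because 2 cholangiocyte markers and 0 hepatocyte markers were among its leading genes. These were Ankrd1, Gpc3, Fgfbp1, Bicc1, Spp1, Ccn2, Spink1, Fos, Gadd45b and Nid1, of which Ankrd1 and Ccn2 are YAP targets. In 50% of the nuclei of this cluster 11 hepatocyte markers were detected, against 10 in 2 clusters named hepatocyte-like. The macrophage-like cluster had 11 by this count and the endothelial-like one 13, so the count does not tell hepatocytes from other types. Exclusion of the unnamed cluster from the hepatocyte-like class rests on this rule. With 1 library per group, it may be the YAP 2-week library and not a cell type.

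Counts were summed per library over all nuclei, hepatocyte-like nuclei and macrophage-like nuclei. Arms were compared with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by arm, 1 coefficient per arm, the quasi-likelihood F test (2-sided) and Benjamini-Hochberg adjustment, with 0.05 as the limit on adjusted p. Classes other than these needed 20 nuclei in every library, which endothelial-like nuclei did not reach (5 in YAP at 2 weeks). No p-value was computed from single nuclei as replicates, while intervals of shares count nuclei and hold counting error only. CPM is the count of a gene scaled to 1e6 summed counts of the same nuclei. Error terms are SD over libraries for CPM and SE of the fit for log2 fold changes. Counts were simulated from 1 mean per gene and the fitted spread. Known changes were put into genes with a mean of at least 10 counts per library, so the rates found do not cover lower counts. The test over all nuclei (12536 genes) found, at the same limit, 63.0% of 4-fold and 6.00% of 2-fold changes of YAP against controls. For LATS it found 66.0% and 5.00%. In hepatocyte-like nuclei (12057 genes) it found 80.0% and 14.0% for YAP and 79.0% and 11.0% for LATS, and in macrophage-like nuclei (2757 genes) 26.0% and 3.00% for YAP and 23.0% and 1.00% for LATS. For YAP against LATS it found 80.0% and 14.5% over all nuclei, 84.0% and 25.0% in hepatocyte-like nuclei, and 68.0% and 8.50% in macrophage-like nuclei. Unchanged genes called in the same runs, for YAP, LATS and YAP against LATS, were 8, 6 and 15 over all nuclei, 6, 16 and 11 in hepatocyte-like and 2, 1 and 10 in macrophage-like nuclei. In hepatocyte-like nuclei of LATS these 16 stood beside 11 and 79 recovered genes, and 22 genes passed in the data, so single calls there are uncertain.

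The marker lists and 34 gene lists, each with at least 3 measured members, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01, and again with the estimated correlation. Shares of nuclei and measures of cycling were compared by exact permutation of libraries between 2 arms, 2-sided. With 10 arrangements of 3 against 2 libraries, or 20 of 3 against 3, the smallest p these tests can give is 0.1. For the share of cycling nuclei, each nucleus was thinned to 1000 counts, shallower nuclei were left out, and a nucleus counted as cycling with at least 2 genes of the G2 and M-phase list. Overlap of the YAP and LATS changes was set beside 100 simulations in which no arm differs and both share the controls. Intervals are exact 95% Clopper-Pearson or Poisson intervals (scipy 1.17.1), a count of 0 is bounded by 3 counts, and both cover counting error only.

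Named genes followed 1 rule: Yap1, Wwtr1, Lats1 and Lats2 first; then, for each of YAP and LATS against controls, up to 10 higher and 10 lower genes by log2 fold change with adjusted p under the limit, a mean of at least 20 CPM in the higher arm and every library of the arm beyond both controls, and up to 5 each way elsewhere. Where fewer than 5 passed, separated genes with at least 50 counts filled the places and are given as not passed. Time courses took 5 monotone genes each way by the log2 ratio of CPM plus 1 at 2 weeks to 4 days. Each list gave 2 to 4 members that passed, or up to 2 with the highest CPM where none did, and 19 liver, cycle and immune genes were always reported. Y-linked genes and Xist were left out of the ranks. Some genes that the rule names are not reported here. The groups, tests, gene lists, marker lists and this rule were fixed before the data were examined.

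Each result was also computed, where the choice touches it, with DESeq2's size factors, DESeq2's Wald test (1.42.0), limma-voom, no filter on low counts, each library left out, at least 500 genes per nucleus, at most 5% mitochondrial counts, doublets kept, time as a block for YAP against LATS, mitochondrial and ribosomal protein genes left out, clustering resolutions of 0.5 and 2, other definitions of cycling, and controls matched to each arm for the overlap. Alternatives added after the data were seen were the barcodes as first designed (without the rules on shared and neighbouring barcodes), no mitochondrial limit, the highest 6% of doublet scores removed, and hepatocyte-like nuclei with the unnamed cluster. The planned settings for macrophage-like nuclei, the lists over all nuclei and cycling in hepatocyte-like nuclei were also added then.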

Results

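The series measured RNA of single nuclei of mouse liver under the labels LATS and YAP, at 4 days, 1 week and 2 weeks, with 2 control libraries labelled tdTomato and YAP no-dox. Each of the 8 groups holds 1 library, so no time point has a replicate, and the arms compared are controls (n = 2), YAP (n = 3) and LATS (n = 3). The tables hold 10387950 and 11018153 counts for the tdTomato and no-dox controls, 6654472, 8672585 and 9252715 for YAP at 4 days, 1 week and 2 weeks, and 10530141, 14110749 and 13061475 for LATS at the same times. Most nuclei were hepatocyte-like. Macrophage-like nuclei numbered 9 and 12 in the controls, and no separate monocyte, neutrophil, lymphocyte, stellate or cholangiocyte cluster formed.

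The labels name LATS and YAP, so the Hippo pathway genes they refer to come first. Lats1 and Lats2, kinases that restrain YAP, had lower mean counts in LATS libraries than in controls, and Lats2 was higher in YAP than in LATS (adjusted p 0.0159 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), but not past that test with time as a block (adjusted p 0.156). Yap1 and Wwtr1, the coactivators, had higher means in YAP libraries, without passing the test. Over all nuclei, Yap1 (chromosome 9, 7931999 to 8004596 in mm10) had 46.6 ± 4.22 CPM in controls, 95.7 ± 37.9 in YAP and 49.7 ± 4.08 in LATS (SD, n = 2, 3 and 3). Wwtr1 (chromosome 3, 57455649 to 57575910) had 15.5 ± 1.95, 36.8 ± 20.6 and 24.5 ± 1.55 CPM. Lats1 (chromosome 10, 7681214 to 7716460) had 28.6 ± 0.211, 31.5 ± 13.5 and 12.6 ± 2.97 CPM, and Lats2 (chromosome 14, 57689662 to 57758388) had 16.8 ± 1.29, 39.0 ± 14.3 and 9.97 ± 1.33 CPM. Against controls none passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: the log2 fold changes (± SE, adjusted p) in YAP were Yap1 (0.82 ± 0.28, 0.165), Wwtr1 (1.01 ± 0.33, 0.147), Lats1 (-0.08 ± 0.30, 0.915) and Lats2 (1.01 ± 0.25, 0.0766), and in LATS Yap1 (0.05 ± 0.27, 0.999), Wwtr1 (0.62 ± 0.32, 0.999), Lats1 (-1.22 ± 0.30, 0.408) and Lats2 (-0.79 ± 0.24, 0.644). The labels do not give the deleted part of any gene, and a transgene has no line of its own, so these counts do not check the labels.

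**Figure D1:**
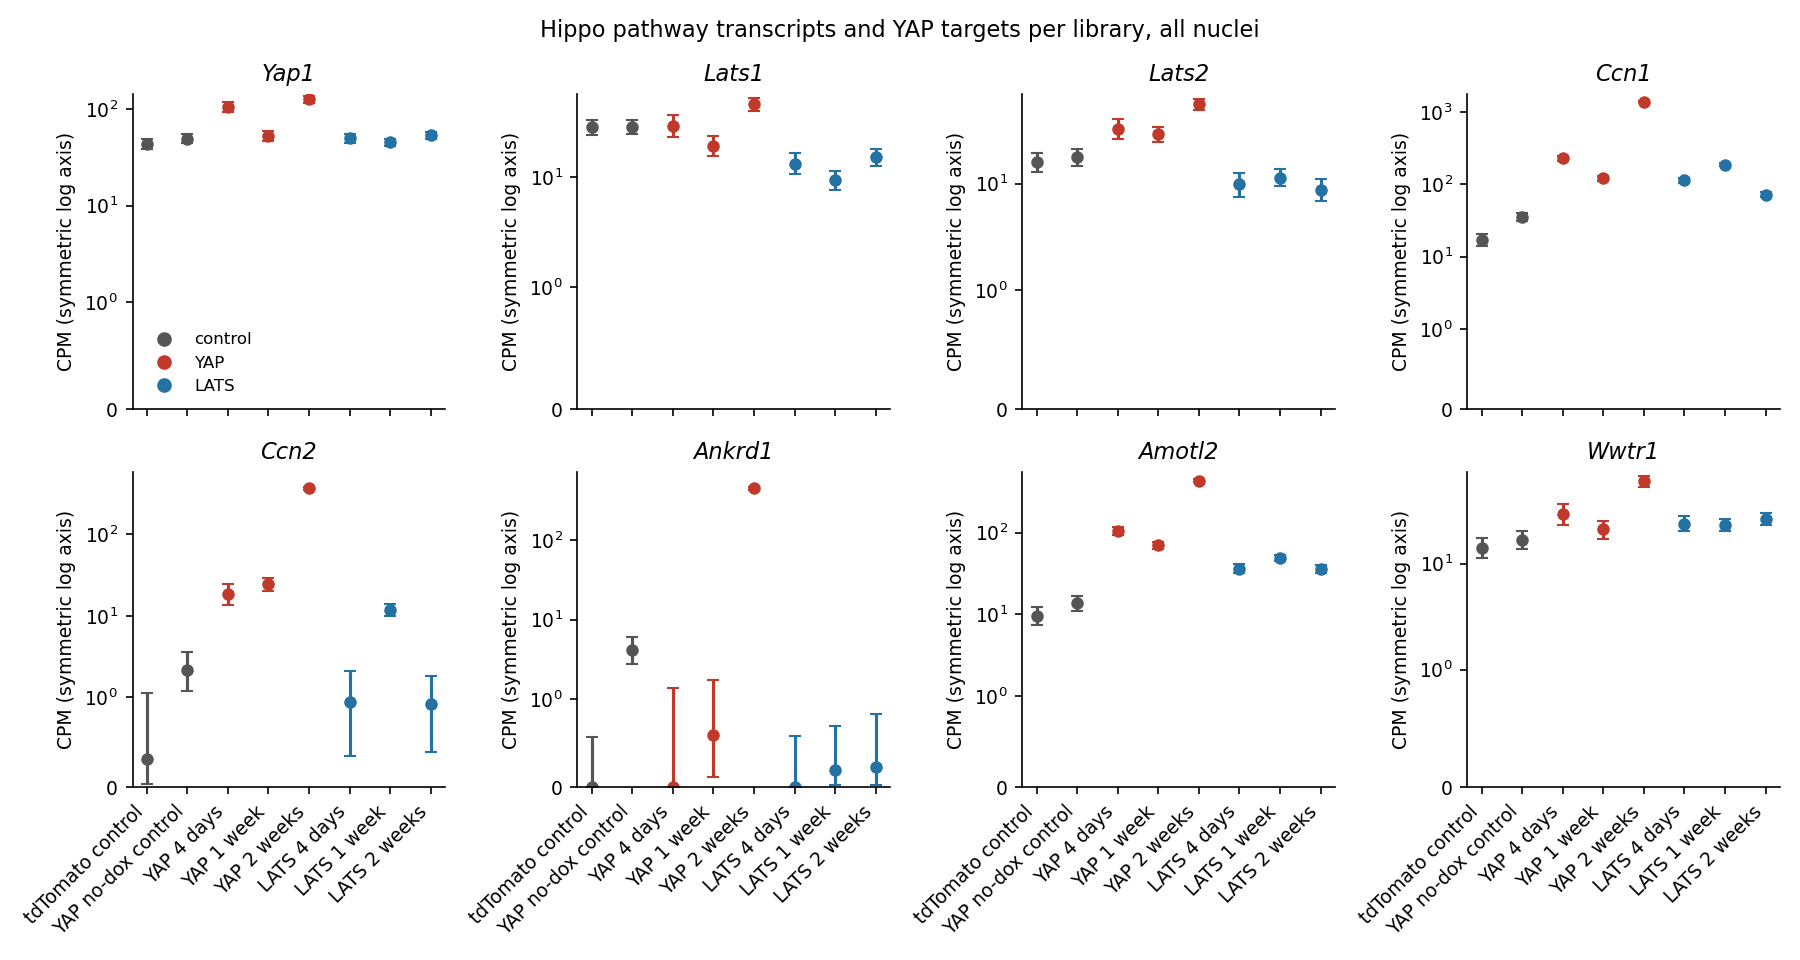
CPM (symmetric log axis) of Yap1, Wwtr1, Lats1, Lats2, Ccn1, Ccn2, Ankrd1 and Amotl2 over all nuclei of each library, with points as library values and bars as exact Poisson 95% intervals of counting error. Lats2 lies at 9.81, 11.4 and 8.73 in the LATS libraries and at 15.8 and 17.7 in the controls, and Ankrd1 reaches 450.1 in YAP at 2 weeks.

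In YAP libraries, Rrm2 and Lig1, genes of DNA replication, and Ect2, Ttk and Hmmr, genes of cell division, rose over all nuclei. Amotl2 and Crim1, YAP target genes, rose with them, as did Cd36, a fatty acid receptor, and Ifit2, an interferon-induced gene. A few metabolic genes fell, among them G6pc, which releases glucose, and Hal and Sds, which break down amino acids, as did the transcription factor Onecut1. The comparison asks what sets the YAP arm apart from controls at any time. Of 12898 genes, 163 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 141 higher and 22 lower, and 2323 had an unadjusted p under 0.05. Without the tdTomato control the count was 0, without the no-dox control 0, without YAP 4 days 3, without YAP 1 week 634, without YAP 2 weeks 328 and without LATS 4 days 68. Every YAP library lay beyond both controls for 33.1% of genes, where chance gives 20%. The largest rises (log2 fold change ± SE, adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) were H2-Q1 (6.53 ± 1.01, 0.0277), Fads3 (5.25 ± 0.85, 0.0303), Ifit2 (4.71 ± 0.71, 0.0277), Cd36 (4.40 ± 0.63, 0.0273), Ect2 (4.00 ± 0.64, 0.0281), Ttk (3.96 ± 0.70, 0.0382), Rrm2 (3.93 ± 0.34, 0.00445), Amotl2 (3.82 ± 0.67, 0.0379), Lig1 (3.66 ± 0.47, 0.0176) and Hmmr (3.65 ± 0.70, 0.0460). The largest falls on the same scale and test, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, included Ugt2b38 (-3.30 ± 0.50, 0.0277), Gm20649 (-2.49 ± 0.36, 0.0273), G6pc (-2.45 ± 0.44, 0.0391), Onecut1 (-2.44 ± 0.31, 0.0176), Aacs (-2.40 ± 0.31, 0.0176), C4a (-2.06 ± 0.37, 0.0389), Hal (-1.95 ± 0.33, 0.0330), Sds (-1.84 ± 0.33, 0.0397) and Slc25a25 (-1.80 ± 0.23, 0.0176). Each of these genes lay beyond both controls in 3 of 3 YAP libraries, as the rule for naming required. Cd36 rose from 9.49 ± 3.53 to 238 ± 158 CPM, Rrm2, a maker of DNA building blocks, from 3.55 ± 0.190 to 62.0 ± 16.3, and Hal fell from 874 ± 0.405 to 247 ± 67.3 (SD).

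Cell cycle genes were called as lists with a preset correlation between genes, and not with the estimated one (adjusted p from 0.279 to 0.660 with an estimated correlation). The G2 and M-phase list had a median log2 fold change of 3.05 (camera adjusted p = 6.29e-34) over 40 genes, of which 19 passed over all genes and 40 adjusted over the list alone. Mki67 and Top2a, markers of dividing cells, rose by 3.50 ± 0.63 and 3.14 ± 0.54 on the log2 scale (adjusted p 0.0401 and 0.0365 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cdc25c, which starts mitosis, had 60 counts in YAP and 1 in controls, a ratio of 61.8 (exact interval 10.7 to 2483). S-phase genes had a median of 2.61 (3.22e-26), with 16 of 34 past the test and 29 higher and 1 lower adjusted over the list alone, among them Uhrf1 (5.01), Cdc6 (4.33), Dtl (4.25) and Gins2 (4.02) (log2 fold changes). YAP/TAZ targets had a median of 1.84 (2.24e-06), with 2 of 15 past the test and 10 adjusted over the list alone. Ccn1, Ccn2 and Ankrd1 among them did not pass: their log2 fold changes, with adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, were Ccn1 (4.16 ± 0.97, 0.0683), Ccn2 (6.44 ± 1.79, 0.102) and Ankrd1 (5.78 ± 2.45, 0.254). The other lists called higher, with median log2 fold change and camera adjusted p, were macrophage and monocyte markers (2.37, 1.13e-08), Kupffer cell genes (1.97, 6.73e-07), chemokines and cytokines (1.85, 4.35e-05), inflammatory monocyte genes (2.41, 0.00307), lipid-associated macrophage genes (1.32, 0.00854), cytoskeleton and junction genes (0.99, 2.57e-06), p53 and senescence genes (0.79, 3.06e-05), TGF-beta and integrin genes (0.87, 0.00171), Notch pathway (1.27, 0.0428), cholangiocyte markers (0.91, 0.0428), interferon-stimulated genes (0.61, 0.0265) and Hippo pathway components (0.51, 0.00485). The lists called lower were periportal genes (-1.04, 6.57e-10), complement and coagulation (-0.61, 7.50e-08), lipogenesis and cholesterol synthesis (-0.80, 8.57e-07), urea cycle and gluconeogenesis (-0.89, 1.23e-06), hepatocyte markers (-0.58, 0.000132), drug-metabolising enzymes (-0.51, 0.000261), mitochondrial transcripts (-0.54, 0.00357), hepatocyte transcription factors (-0.24, 0.00803), acute-phase genes (-0.53, 0.00854), unfolded protein response (-0.38, 0.0232) and pericentral genes (-0.40, 0.0499). The median percent of counts from Rn18s, the 18S ribosomal RNA gene, was beyond both controls in every YAP library: 16.1, 11.2 and 10.3 at 4 days, 1 week and 2 weeks, against 5.49 and 9.78 in the controls and 12.2, 9.33 and 8.71 in LATS. Of the 26 lists called, 18 stayed called with each library left out in turn. Without YAP 2 weeks, the Notch pathway, cholangiocyte markers, interferon-stimulated genes, Hippo pathway components, drug-metabolising enzymes, hepatocyte transcription factors and pericentral genes were not called (adjusted p from 0.0580 to 0.798). Notch was also lost without the tdTomato control or YAP 1 week, cholangiocyte markers without the tdTomato control or LATS 2 weeks, and acute-phase genes without the tdTomato control or YAP 4 days. Pericentral genes were also lost without the no-dox control, LATS 4 days or LATS 2 weeks, and interferon-stimulated genes without the no-dox control. Relative to the other libraries, abundant hepatocyte markers had a median log2 ratio of -0.29, 0.22 and -0.78 in YAP at 4 days, 1 week and 2 weeks, and 0.23 and 0.26 in the controls. With the preset correlation 26 of 43 lists were called, 15 higher and 11 lower, and none of them with the estimated correlation (adjusted p from 0.279 to 0.660 with an estimated correlation).

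Several genes of liver identity and of immune cells were followed whether or not they moved, and none of them passed over all nuclei. Afp, a fetal liver gene, Spp1 and Sox9, ductal genes, and Cdkn1a, a brake on the cell cycle, had higher means in YAP, as did Clec4f and Ccl2, a chemokine gene. Alb and Hnf4a, markers of hepatocytes, showed no change detectable at this spread in either arm. For YAP the log2 fold changes (± SE, adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) were Afp (3.16 ± 0.89, 0.106), Spp1 (3.64 ± 1.32, 0.188), Sox9 (1.01 ± 0.73, 0.507), Cdkn1a (3.30 ± 0.79, 0.0732), Clec4f (2.11 ± 0.56, 0.0891), Ccr2 (3.59 ± 1.52, 0.257), Cyp7a1 (0.20 ± 0.57, 0.878), Cyp2e1 (-0.24 ± 1.03, 0.922), Alb (-0.19 ± 0.32, 0.789) and Hnf4a (0.09 ± 0.25, 0.877). For LATS, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, they were Afp (0.66 ± 0.89, 0.999), Spp1 (0.30 ± 1.15, 0.999), Sox9 (-0.26 ± 0.71, 0.999), Cdkn1a (1.64 ± 0.76, 0.999), Clec4f (1.05 ± 0.53, 0.999), Ccr2 (1.00 ± 1.60, 0.999), Cyp7a1 (1.52 ± 0.59, 0.878), Cyp2e1 (0.48 ± 1.05, 0.999), Alb (-0.50 ± 0.32, 0.999) and Hnf4a (0.37 ± 0.25, 0.999). Also for LATS, and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, they were Ccn1 (2.19 ± 0.88, 0.911), Ccn2 (1.88 ± 1.72, 0.999), Amotl2 (1.75 ± 0.61, 0.793), Mki67 (2.39 ± 0.60, 0.422) and Top2a (1.67 ± 0.51, 0.645). Ccl2 had 0 and 2 counts in the controls, 10, 19 and 93 in YAP at 4 days, 1 week and 2 weeks, and 1, 10 and 2 in LATS, so most of its YAP counts came from 1 library. Krt19, a ductal keratin gene, had 2 counts in controls and 4 in YAP, a ratio of 2.06 (exact interval 0.295 to 22.8), and the monocyte gene Ly6c2 reached at most 0.78 CPM in any library.

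In LATS libraries, a small set of genes passed over all nuclei, and no single gene of the G2 and M-phase list did. Rps13-ps1, a pseudogene of a ribosomal protein gene, rose, and Rnaset2b, a ribonuclease gene, fell. Division genes were called higher as a list, and periportal, urea cycle and lipid synthesis genes lower, but none of these lists was called with the estimated correlation (adjusted p from 0.430 to 0.881 with an estimated correlation). The comparison asks the same of the LATS arm. Of 12898 genes, 4 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 higher and 1 lower, and 653 had an unadjusted p under 0.05. The count was 1 without the tdTomato control, 2 without the no-dox control, 9 without YAP 1 week, 55 without YAP 2 weeks, 2 without LATS 4 days, 1 without LATS 1 week and 1 without LATS 2 weeks. Every LATS library lay beyond both controls for 26.5% of genes, against 20% by chance. The genes were Rps13-ps1 (10.10 ± 0.56, adjusted p 0.000152 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Gm8730 (2.41 ± 0.24, 0.010), Rnaset2b (-4.52 ± 0.41, 0.00561) and Gm46516 (1.96 ± 0.24, 0.0491), the last below 20 CPM and named after its values were seen. Rps13-ps1 had 4801 counts in LATS and 2 in controls, a ratio of 1224 (exact interval 339 to 10106). It shares reads with Rps13 and other copies, so its level is uncertain. Genes apart in all libraries that did not pass, with log2 fold change, SE and adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, included Mt2 (4.30 ± 1.79, 0.958), Abhd1 (3.55 ± 0.49, 0.0521), Hmmr (3.46 ± 0.69, 0.205), Cib3 (-3.30 ± 0.61, 0.164), Rps13-ps2 (-2.46 ± 0.32, 0.0521), Rps13 (-2.28 ± 0.31, 0.0521) and Serpine2 (-1.89 ± 0.58, 0.644).

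The G2 and M-phase list had a median log2 fold change of 1.93 in LATS (camera adjusted p = 1.51e-43), with 0 of 40 genes past the gene-level test and 36 adjusted over the list alone. Mki67 had 55.3 ± 27.4 CPM in LATS and 10.3 ± 9.15 in controls, and did not pass. S-phase genes had a median of 0.66 (3.88e-09) and YAP/TAZ targets of 0.43 (0.0442), with 3 and 1 genes past the test adjusted over the list alone. The other lists called higher (median log2 fold change, camera adjusted p) were macrophage and monocyte markers (1.08, 0.000858), Kupffer cell genes (0.87, 0.000274), p53 and senescence genes (0.52, 0.0211), pericentral genes (0.47, 0.0272), interferon-stimulated genes (0.40, 0.00863), lipid-associated macrophage genes (0.35, 0.0223) and fatty acid oxidation and ketogenesis (0.13, 0.0430). The lists called lower were lipogenesis and cholesterol synthesis (-0.70, 7.64e-13), periportal genes (-0.69, 6.66e-11), urea cycle and gluconeogenesis (-0.55, 2.59e-07), immediate early and heat shock genes (-0.28, 0.0430), complement and coagulation (-0.24, 0.00863), hepatocyte markers (-0.18, 0.0272) and ribosomal protein genes (-0.14, 0.00812). Of 43 lists 17 were called, 10 higher and 7 lower, but 9 without the tdTomato control and 10 without LATS 1 week. Only 5 were called with each library left out in turn: G2 and M-phase, S-phase, periportal, lipogenesis, and urea cycle genes. None was called with the estimated correlation (adjusted p from 0.430 to 0.881 with an estimated correlation).

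**Figure D2:**
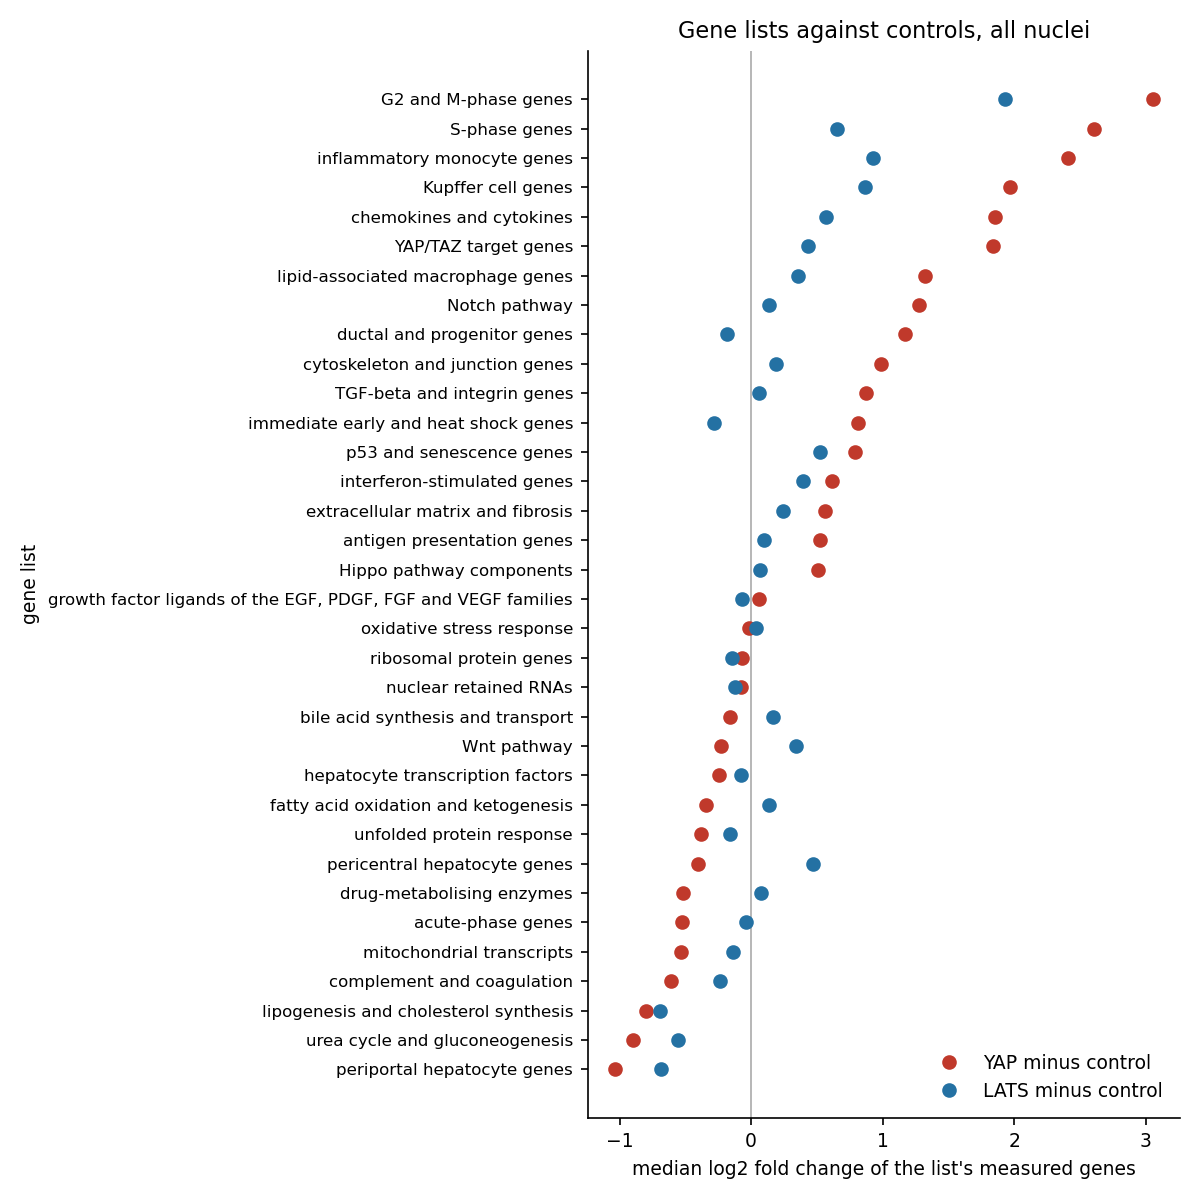
Median log2 fold change of the members of each of the 34 gene lists over all nuclei, YAP minus controls and LATS minus controls, with 1 point per list and arm. G2 and M-phase genes lie at 3.05 in YAP and 1.93 in LATS, and periportal genes at -1.04 and -0.69.

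Within hepatocyte-like nuclei, the YAP targets Ccn1 and Ccn2, matricellular protein genes, and Amotl2 and Crim1 rose in YAP. Csf1, a growth factor for macrophages, rose too. Onecut1, G6pc and Ugt2b38 fell, as they had over all nuclei. This class spans 10 clusters in proportions that differ between libraries, so the comparison mixes states. YAP at 2 weeks gave only 65 such nuclei, those left outside the unnamed cluster, whose leading genes include the YAP targets Ankrd1 and Ccn2. Its values here are thus of a selected remainder. The fullest cluster was 3 in YAP 4 days, 6 in YAP 1 week, 10 in YAP 2 weeks, 4 in the tdTomato control and 1 in the no-dox control. Median percents of counts from Rn18s in these clusters were 34.5, 13.2, 2.61, 5.46 and 22.2 in that order. Near ties were the no-dox control, with 337 nuclei in cluster 1 and 336 in cluster 4, and YAP 1 week, with 557 in cluster 6 and 548 in cluster 1. Of 12366 genes, 88 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 73 higher and 15 lower, with 1303 at an unadjusted p under 0.05. Without the tdTomato control 5 passed, without the no-dox control 4, without YAP 4 days 7, without YAP 1 week 46, without YAP 2 weeks 299 and without LATS 2 weeks 35. With the unnamed cluster, an alternative chosen after the data were seen, 130 passed, of which 57 were among the 88. The largest rises (log2 fold change ± SE, adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) were Ccn2 (6.25 ± 1.23, 0.0469), H2-Q1 (5.63 ± 0.63, 0.00312), Ifit2 (4.90 ± 0.74, 0.0185), Fads3 (4.72 ± 0.52, 0.00299), Cd36 (4.39 ± 0.56, 0.00928), Rrm2 (3.67 ± 0.56, 0.0185), Hmmr (3.67 ± 0.71, 0.0433), Csf1 (3.62 ± 0.50, 0.0145), Ccn1 (3.30 ± 0.58, 0.0289) and Lig1 (3.29 ± 0.55, 0.0279). The largest falls, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, were Gm20649 (-2.92 ± 0.29, 0.00161), Onecut1 (-2.68 ± 0.27, 0.00161), Serpina4-ps1 (-2.52 ± 0.49, 0.0441), Ugt2b38 (-2.49 ± 0.42, 0.0285), Aacs (-2.17 ± 0.28, 0.0101), Gm4956 (-2.12 ± 0.31, 0.0161), G6pc (-2.05 ± 0.37, 0.0336), Wsb1 (-1.92 ± 0.36, 0.0384), Tff3 (-1.90 ± 0.35, 0.0373) and Cyp2u1 (-1.70 ± 0.27, 0.0211). Each gene named lay beyond both controls in 3 of 3 YAP libraries, which the rule for naming required of the largest rises and falls. Ccn1 had 26.1 ± 13 CPM in controls and 300.4 ± 213 in YAP, and Amotl2 10.9 ± 2.65 and 98.5 ± 24.2 (SD). Every YAP library lay beyond both controls for 21.8% of genes, near the 20% of chance. YAP/TAZ targets had a median log2 fold change of 1.43 (camera adjusted p = 6.44e-08), with 4 of 14 past the test and 5 adjusted over the list alone. G2 and M-phase genes had 2.90 (3.26e-17) with 6 and 39, and S-phase genes 2.13 (3.26e-17) with 7 and 29. Of 40 lists 20 were called, 13 higher and 7 lower, 13 of the 20 with each library left out in turn, and none with the estimated correlation (adjusted p from 0.264 to 0.562 with an estimated correlation). Macrophage markers had a median of 1.81 in these nuclei, although they mark another cell type.

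In hepatocyte-like nuclei of LATS, Amotl2, Crim1 and Cd36 rose, and Acly and Aacs, genes of lipid synthesis, fell. Psmb5, a proteasome gene, also fell. Rps13 and Rps13-ps2 fell while Rps13-ps1 rose, and since they share reads each value is uncertain. The fullest cluster was 10 in LATS 4 days, 1 in LATS 1 week and 2 in LATS 2 weeks, against 4 and 1 in the controls. The median percent of counts from Rn18s in these clusters was 2.61, 22.2, 11.2, 5.46 and 22.2 in that order. LATS 1 week was near a tie, with 692 nuclei in cluster 1 and 654 in cluster 4, as was the no-dox control with 337 and 336. Of 12366 genes, 22 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13 higher and 9 lower, with 763 at an unadjusted p under 0.05. Without the tdTomato control 5 passed, without the no-dox control 3, without YAP 4 days 12, without YAP 2 weeks 93, without LATS 4 days 13, without LATS 1 week 4, without LATS 2 weeks 4 and with the unnamed cluster 4. The rises at 20 CPM or more (log2 fold change ± SE, adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) were Rps13-ps1 (10.04 ± 0.52, 4.62e-06), Cd36 (3.60 ± 0.54, 0.0214), Abhd1 (3.53 ± 0.48, 0.0190), Crim1 (2.71 ± 0.42, 0.0249), Gm3375 (2.45 ± 0.37, 0.0214), Gm8730 (2.41 ± 0.24, 0.00159) and Amotl2 (1.84 ± 0.27, 0.0208). The falls at that level, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, were Rnaset2b (-4.45 ± 0.40, 0.00106), Rps13-ps2 (-2.46 ± 0.33, 0.0190), Rps13 (-2.27 ± 0.36, 0.0290), Aacs (-1.67 ± 0.25, 0.0214), Psmb5 (-1.51 ± 0.25, 0.0370) and Acly (-1.39 ± 0.22, 0.0290). All of these lay beyond both controls in 3 of 3 LATS libraries, as the rule for naming required. Rps13-ps1 had 2 counts in controls, a ratio of 1199 (exact interval 332 to 9899.5). Amotl2 rose from 10.9 ± 2.65 to 40.2 ± 7.19 CPM and Acly fell from 169 ± 26.0 to 65.8 ± 13.1 (SD). G2 and M-phase genes had a median log2 fold change of 2.13 (camera adjusted p = 6.35e-24), with 0 of 40 past the test and 33 adjusted over the list alone. Periportal genes had -0.67 (8.53e-12), lipogenesis -0.70 (6.45e-11) and YAP/TAZ targets 0.51 (0.0166), the last not called without the tdTomato control (0.314) or LATS 1 week (0.0935). Of 40 lists 18 were called, 11 higher and 7 lower, 7 of the 18 with each library left out in turn, and none with the estimated correlation (adjusted p from 0.380 to 0.797 with an estimated correlation). Among the 7 lists kept with each library left out were macrophage and monocyte markers and Kupffer cell genes, although they mark another cell type. Every LATS library lay beyond both controls for 28.1% of genes, against 20% by chance.

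Macrophage-like nuclei expressed Clec4f, a Kupffer cell lectin, at 2537 ± 17.7 CPM in controls, 1747 ± 481 in YAP and 2230.3 ± 551 in LATS (SD, n = 2, 3 and 3). No gene passed in YAP or in LATS against controls. Between YAP and LATS, Adamdec1, a protease gene, was higher in YAP, and 4 urinary protein genes of the Mup family, made by hepatocytes, were higher in LATS. Hepatocyte markers summed to 29004 CPM in this cluster over all libraries, beside 10134 CPM of macrophage markers. Differences here in Mup genes and in lists of hepatocyte genes therefore cannot be assigned to macrophages. Adamdec1 lies on chromosome 14 (68563380 to 68582095), as does Lats2. The controls held 9 and 12 such nuclei, and the test on simulated counts found 26.0% of 4-fold changes there for YAP. By edgeR's quasi-likelihood test 0 of 3006 genes passed for YAP and 0 for LATS, with 189 and 185 at an unadjusted p under 0.05. DESeq2's Wald test gave 0 and 2 and limma-voom 0 and 0, and the counts at an unadjusted p under 0.05 were 267 and 255 by DESeq2 and 130 and 114 by limma-voom. Without YAP 1 week the YAP count was 3, and without YAP 2 weeks the LATS count was 2. YAP against LATS gave 7 genes: 11 without the tdTomato control, 14 without the no-dox control, 45 without YAP 1 week, 3 without LATS 4 days, 0 without LATS 1 week, 2 without LATS 2 weeks and 38 with time as a block. With log2 fold change ± SE and adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, they were Rps13 (2.59 ± 0.43, 0.0102), Mup15 (-5.04 ± 0.80, 0.00759), Mup16 (-4.74 ± 0.69, 0.00478), Mup17 (-4.66 ± 0.71, 0.00598) and Mup14 (-2.49 ± 0.46, 0.0297), and Adamdec1 and Rps13-ps1 (adjusted p 0.0416 and 0.00478), each with no counts in the lower arm. Adamdec1 had 121 ± 17.2 CPM in YAP, at least 22.2-fold higher by a floor of 3 counts over the LATS group, and Rps13-ps1 234 ± 72.4 CPM in LATS, at least 52.6-fold higher than YAP by the same floor. No list in this class was called with the estimated correlation, so the following rest on the preset one (adjusted p = 0.809 for each with an estimated correlation for YAP, adjusted p = 0.940 for each with an estimated correlation for LATS and adjusted p from 0.468 to 0.594 with an estimated correlation between them). Lists called in YAP against controls (median log2 fold change, camera adjusted p) were periportal genes (-0.67, 0.000565), antigen presentation (-0.70, 0.000565) and p53 and senescence genes (1.23, 0.0109), 3 of 34. That count was 14 without the tdTomato control, 1 without YAP 4 days, 10 without YAP 1 week, 8 without YAP 2 weeks, and 6, 7 and 6 without LATS 4 days, 1 week and 2 weeks. In LATS 6 lists were called: immediate early and heat shock genes (-1.20, 0.000510), antigen presentation (-0.48, 0.0173), S-phase genes (-2.07, 0.0337), drug-metabolising enzymes (0.57, 0.0130), fatty acid oxidation and ketogenesis (0.59, 0.0246) and pericentral genes (1.18, 0.0337). That count was 3 without the tdTomato control, 11 without the no-dox control and 3 without LATS 1 week. With each library left out in turn, only antigen presentation stayed called in YAP, and none of the 6 in LATS did. Between YAP and LATS 16 of 34 were called, among them G2 and M-phase genes (3.11, 9.28e-06), S-phase genes (2.54, 1.90e-05) and hepatocyte markers (-0.67, 7.96e-06). With each library left out in turn 9 of the 16 stayed called, without S-phase genes.

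YAP and LATS libraries differed in a few single genes, of which 1 passed with time as a block, and in lists that were not called with the estimated correlation (adjusted p from 0.370 to 0.501 with an estimated correlation). Tead1, a DNA-binding partner of YAP, and Lats2 were higher in YAP, as were the replication genes Hells and Lig1. Abhd1, a hydrolase gene, and Wdfy1, an endosomal protein gene, were higher in LATS. Over all nuclei 32 genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 24 higher in YAP and 8 lower, with 2247 at an unadjusted p under 0.05. The count was 15 without the tdTomato control, 15 without the no-dox control, 4 without YAP 4 days, 134 without YAP 1 week, 80 without YAP 2 weeks, and 1, 10 and 9 without LATS 4 days, 1 week and 2 weeks. With time as a block it was also 1, and that gene, Rps13-ps1, was lower in YAP. The genes (log2 fold change of YAP over LATS ± SE, adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) included Fads3 (4.99 ± 0.69, 0.0249), Tead1 (4.01 ± 0.59, 0.0374), Hells (2.55 ± 0.32, 0.0159), Lig1 (2.47 ± 0.36, 0.0374), Rps13-ps2 (2.46 ± 0.31, 0.0159) and Lats2 (1.80 ± 0.22, 0.0159) above 0, and Rps13-ps1 (-9.30 ± 0.46, 4.48e-05), Abhd1 (-4.35 ± 0.46, 0.0111), Gm3375 (-2.80 ± 0.32, 0.0135), Gm8730 (-2.35 ± 0.21, 0.00550) and Wdfy1 (-2.07 ± 0.28, 0.0249) below 0. Each set all 3 YAP libraries apart from all 3 LATS libraries, which the rule for naming required of all but Lats2. Of all genes tested 20.4% did so, where chance gives 10%. S-phase genes had a median of 1.72 (camera adjusted p = 1.37e-22), with 7 of 34 past the test and 27 adjusted over the list alone. G2 and M-phase genes had 1.11 (3.31e-11), YAP/TAZ targets 1.80 (8.80e-05) and pericentral genes -0.86 (5.69e-05). Of 43 lists 27 were called, 16 without YAP 2 weeks, 15 with each library left out in turn, these 4 among them, and none with the estimated correlation (adjusted p from 0.370 to 0.501 with an estimated correlation).

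In hepatocyte-like nuclei Bicc1, an RNA-binding protein gene of bile ducts, Tead1, Csf1 and Ifit2 were higher in YAP than in LATS, and Onecut1 was lower. The fullest clusters were 3, 6 and 10 in YAP and 10, 1 and 2 in LATS, with near ties in the 1-week library of each arm. Of 12366 genes 34 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 23 higher and 11 lower, with 1224 at an unadjusted p under 0.05. The count was 6 without YAP 4 days, 20 without YAP 1 week, 89 without YAP 2 weeks, 11 without LATS 4 days, 5 without LATS 2 weeks, 17 with the unnamed cluster and 17 with time as a block, which 7 of the 15 named calls passed. The genes (log2 fold change ± SE, adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) included Bicc1 (4.37 ± 0.64, 0.0177), Fads3 (4.37 ± 0.41, 0.00126), Tead1 (3.71 ± 0.49, 0.0111), Ifit2 (2.94 ± 0.52, 0.0492), Csf1 (2.52 ± 0.39, 0.0199) and Lats2 (1.64 ± 0.22, 0.0111) higher, and Rps13-ps1 (-9.37 ± 0.49, 4.27e-06), Abhd1 (-4.42 ± 0.55, 0.00775), Gm3375 (-2.57 ± 0.36, 0.0142), Gm8730 (-2.35 ± 0.23, 0.00126), Wdfy1 (-2.05 ± 0.32, 0.0199) and Onecut1 (-1.52 ± 0.25, 0.0303) lower. S-phase genes had a median of 1.29 (camera adjusted p = 2.45e-10), and G2 and M-phase genes were not called (0.228). Of 40 lists 16 were called, 10 without YAP 2 weeks, 5 with each library left out in turn, S-phase genes among them, and none with the estimated correlation (adjusted p from 0.465 to 0.687 with an estimated correlation). Every list in any class whose median, mean and test differed in sign was one not called.

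Macrophage-like nuclei, a class led by Kupffer cell genes, made up a larger share in the YAP libraries than in controls. Their share was also high in LATS at 1 week. Endothelial-like shares varied within each arm about similar means, and hepatocyte-like nuclei were few in YAP at 2 weeks. Macrophage-like shares (exact 95% intervals) were 0.585% (0.268 to 1.11) and 0.745% (0.386 to 1.30) in the tdTomato and no-dox controls, 2.39% (1.37 to 3.85), 5.33% (4.46 to 6.33) and 4.37% (3.18 to 5.84) in YAP at 4 days, 1 week and 2 weeks, and 1.00% (0.573 to 1.62), 4.69% (3.98 to 5.48) and 0.858% (0.538 to 1.30) in LATS. The YAP mean exceeded controls by 3.36 points (exact 2-sided permutation p = 0.2, adjusted 0.6; the smallest possible is 0.1). LATS exceeded controls by 1.52 points (exact permutation p = 0.5, adjusted 1), and by 0.264 without LATS 1 week and 2.44 at clustering resolution 2. YAP exceeded LATS by 1.85 points (exact permutation p = 0.3), and by 3.10 without LATS 1 week, 1.19 without LATS 2 weeks and 1.20 without YAP 1 week. It did so by 1.02 at resolution 0.5 and 0.762 at resolution 2. At resolution 0.5 no endothelial-like cluster formed, and the cluster named macrophage-like also held endothelial markers (4583 CPM beside 6599 of macrophage markers, against 1575 and 10134 at resolution 1). Shares in that mixed cluster were 1.76% and 2.42% in the controls, 4.48%, 3.83% and 4.77% in YAP and 6.22% in LATS at 1 week. At resolution 2 the macrophage-like shares in the same order were 0.585% and 1.12%, 3.59%, 2.88% and 5.69%, and 7.19%. Each YAP library lay above both controls at resolutions 1 and 2, but the order of YAP and LATS at 1 week turned. Hepatocyte-like shares were 92.6% to 98.2% outside YAP 2 weeks, where 6.60% (5.13 to 8.33) was hepatocyte-like and 88.5% lay in the unnamed cluster. That split rests on the naming rule. In the unnamed cluster 11 hepatocyte markers were detected in 50% of nuclei, but so were 11 in the macrophage-like and 13 in the endothelial-like cluster. This count therefore does not tell the type of the unnamed cluster. The hepatocyte-like difference of YAP from controls was -33.3 points (exact permutation p = 0.5), and -4.39 without YAP 2 weeks and -18.2 with barcodes as first designed. That of LATS was -1.59 (exact permutation p = 0.8), and 0.174 without LATS 1 week, -2.42 without LATS 4 days, -2.54 without LATS 2 weeks, -3.08 at resolution 2 and 0.0249 with barcodes as first designed. Endothelial-like shares were 1.17% and 1.86% in the controls, 2.09%, 1.55% and 0.508% in YAP, and 1.13%, 2.41% and 1.09% in LATS. Endothelial-like differences were -0.134 and 0.0248 points for YAP and LATS against controls (exact permutation p = 0.9 and 1), and ranged from -0.489 to 0.304 and from -0.408 to 0.371 with each library left out. Over the other settings they ranged from -0.393 to 0.0531 and from 0.0236 to 0.302.

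**Figure D3:**
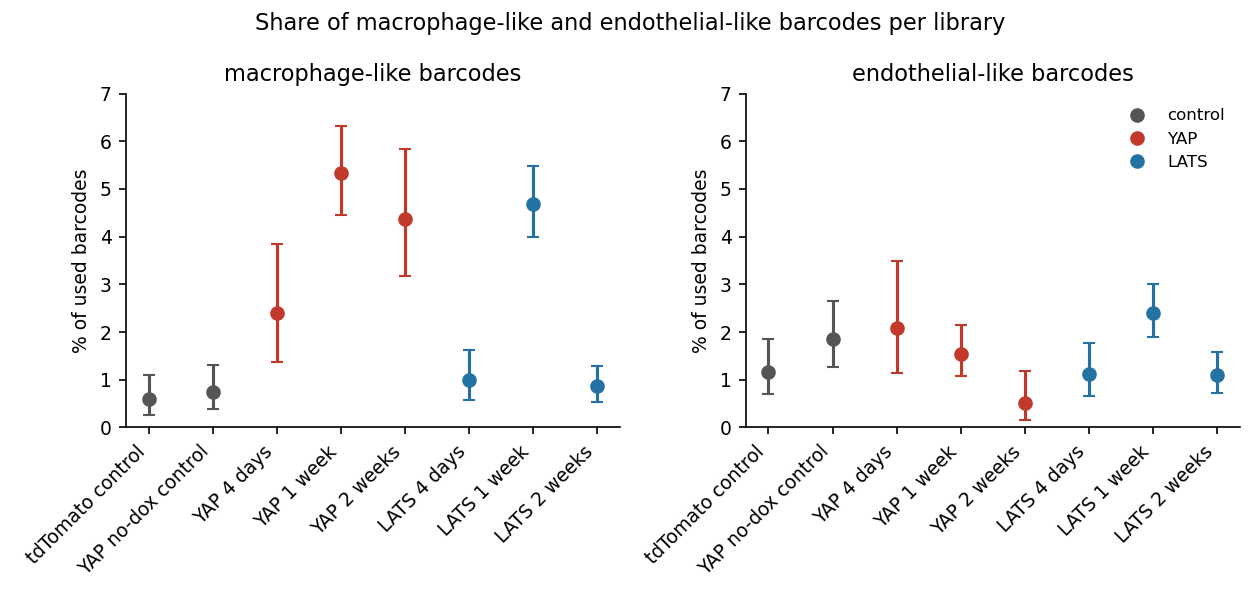
Percent of nuclei that were macrophage-like and endothelial-like in each library, with points as library values and bars as exact 95% Clopper-Pearson intervals. At resolution 1, macrophage-like shares lie at 5.33% in YAP at 1 week and 4.69% in LATS at 1 week, and below 1% in both controls.

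Transcripts of G2 and M-phase genes, which drive division, were more abundant in every YAP and LATS library than in both controls. S-phase transcripts were more abundant in YAP, while LATS libraries overlapped with controls. Summed G2 and M-phase counts were 272 and 96.3 CPM in controls, 1792, 1119 and 1416 in YAP at 4 days, 1 week and 2 weeks, and 396, 825 and 705 in LATS. The YAP mean of 1442 CPM compared with 184 in controls (exact 2-sided permutation p = 0.1, the smallest possible), and the LATS mean was 642 (exact permutation p = 0.2). Summed S-phase counts averaged 872 CPM in YAP, 357 in controls and 408 in LATS (exact permutation p = 0.1 for YAP and 0.4 for LATS against controls). After thinning, 1.48% and 1.17% of control nuclei, 22.5%, 12.6% and 22.9% of YAP nuclei and 6.61%, 12.9% and 10.4% of LATS nuclei held at least 2 genes of the list. The means of YAP, LATS and controls, 19.4%, 9.96% and 1.33%, were 31.5%, 18.0% and 3.38% without thinning, 41.8%, 25.7% and 6.41% with at least 1 gene, and 10.1%, 5.53% and 0.781% with at least 3. Among endothelial-like nuclei, taken as another cell type for comparison, the pooled shares were 1 of 38 (2.63%) in controls, 5 of 40 (12.5%) in YAP and 11 of 101 (10.9%) in LATS. Their median depths were 4483.5, 2010.5 and 3047 counts, and those of hepatocyte-like nuclei 3270.5, 2305 and 3038. The intervals of endothelial-like nuclei overlap, so whether these nuclei were also higher cannot be told. The shares of cycling nuclei alone are therefore not read as dividing nuclei. A separate cluster of 386 hepatocyte-like nuclei led by Cenpf, Prc1, Hmmr, Top2a, Cenpe and Tpx2 held 9 and 5 control nuclei, 68, 81 and 0 of YAP at 4 days, 1 week and 2 weeks, and 18, 118 and 87 of LATS. In hepatocyte-like nuclei the shares were 19.5%, 12.2% and 2.17% in YAP, the last 1 of 46 nuclei, and their mean of 11.3% compared with 0.987% in controls and 9.16% in LATS (exact permutation p = 0.2 and 0.2 against controls). Those 46 nuclei lay outside the unnamed cluster, and over all nuclei of that library the share was 22.9%. Without YAP 4 days the YAP mean in hepatocyte-like nuclei was 7.19%. The means of YAP, LATS and controls in these nuclei were 24.1%, 17.8% and 3.19% without thinning, where YAP at 2 weeks was at 26.2%. They were 33.4%, 25.1% and 6.401% with at least 1 gene, and 6.04%, 5.32% and 0.707% with at least 3.

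**Figure D4:**
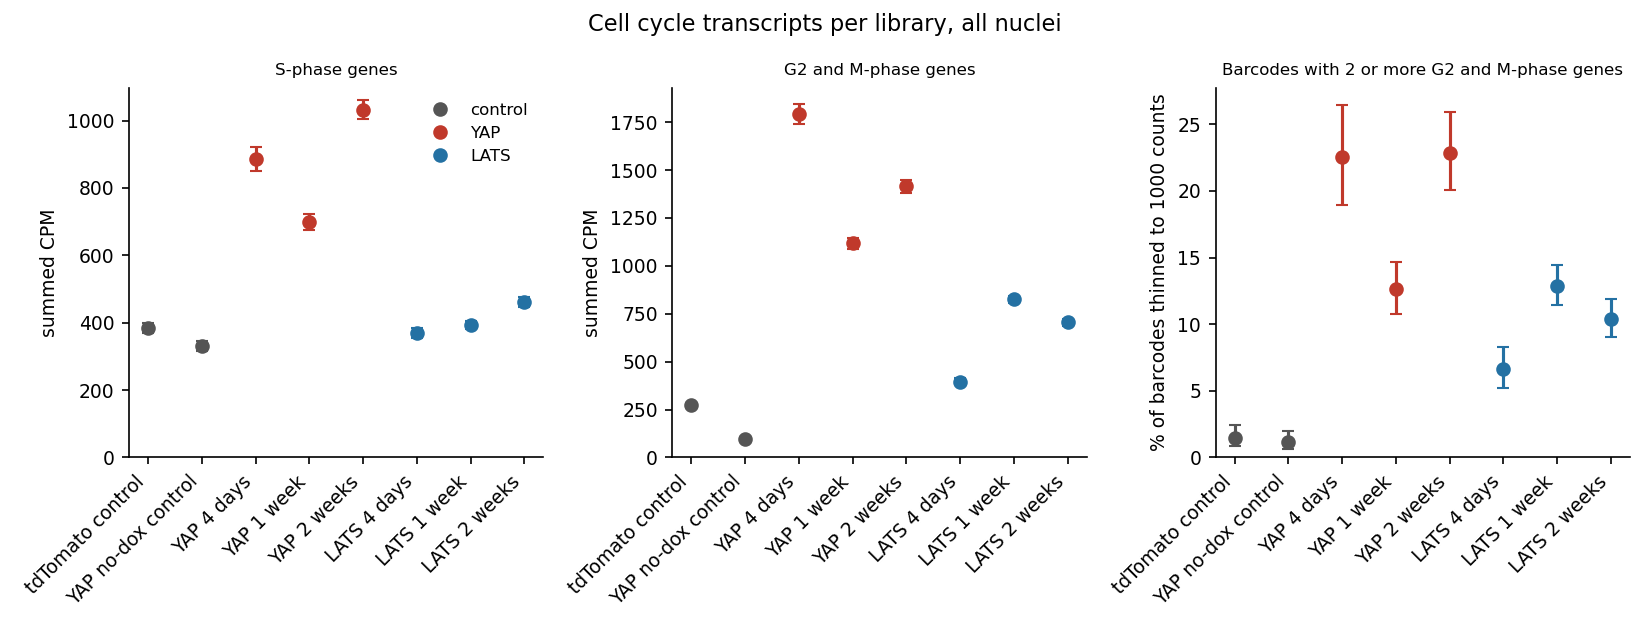
Summed CPM of S-phase genes and of G2 and M-phase genes, and percent of nuclei with at least 2 G2 and M-phase genes after thinning to 1000 counts, for each library on linear axes from 0. G2 and M-phase counts lie between 1119 and 1792 CPM in YAP, between 396 and 825 in LATS and at 272 and 96.3 in controls.

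Within the YAP arm, Ankrd1, a YAP target, Jag1, a Notch ligand, Gpc3, a fetal liver proteoglycan gene, and Sox4, a progenitor transcription factor, had their highest values at 2 weeks. Mup11, Mup15, Mup16 and Mup17, urinary protein genes, had their lowest there. Within the LATS arm, Cish, a cytokine signalling inhibitor, and Phlda1 had their highest values at 2 weeks, and the metallothioneins Mt1 and Mt2 their lowest. Each time point is 1 library, so these are differences between libraries without a test, in genes picked for such a course. The YAP 2-week library is the one with 88.5% of its nuclei in the unnamed cluster. CPM over all nuclei at 4 days, 1 week and 2 weeks of YAP were, for the genes with increasing values, Ankrd1 (0, 0.591 and 450.1), Jag1 (0, 3.55 and 171), Gpc3 (4.17, 9.65 and 555), Emp1 (0.379, 3.35 and 142) and Sox4 (0.379, 1.38 and 109.8). For those with decreasing values they were Mup17 (347, 108 and 1.65), Mup15 (116, 27.8 and 0.206), Mup11 (321, 268 and 3.10), Mup16 (195, 78.4 and 2.68) and Elovl3 (60.3, 44.9 and 0.206), of which the Mup genes share reads with near-identical copies. In LATS the increasing genes were Cish (2.69, 55.7 and 70.7), Phlda1 (114, 367 and 588), Foxq1 (30.4, 97.4 and 146), Cyp26a1 (11.6, 12 and 52.2) and Arid5b (46.2, 149 and 191), and the decreasing ones Mt1 (177, 75.5 and 7.47), Mt2 (64.7, 53.3 and 2.64), Gm29966 (99.1, 29.2 and 15.3), Ccnb1ip1 (60.8, 30.1 and 10.1) and Gm43189 (14.2, 5.40 and 2.18). Spp1, a ductal and macrophage gene, reached 1304 (95% interval 1272 to 1337) CPM in YAP at 2 weeks and Sox9 99.7 (95% interval 91.0 to 109), while Cyp2e1, a pericentral enzyme, was at 79.7 (95% interval 71.9 to 88.0). The monocyte receptor gene Ccr2 was at 16.5 (95% interval 13.1 to 20.5) CPM there and its ligand gene Ccl2 at 19.2 (95% interval 15.5 to 23.5).

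Amotl2, Crim1 and Cd36 rose in hepatocyte-like nuclei of both arms, and Aacs fell in both. Genes past the test in the same direction in both arms numbered 5 higher and 1 lower in hepatocyte-like nuclei, where independent lists give 0.0767 and 0.0109, and none went opposite ways. With 1 control matched to each arm, 4 genes passed for YAP and 3 for LATS, and 0 were shared in either direction. Over all nuclei 1 gene was higher in both (0.0328 for independent lists). Both arms share the controls, so the fold changes correlate without any effect. Across genes, which are not independent replicates, r was 0.564 (rho 0.509) over all nuclei against 0.603 (0.583 to 0.628) in simulations without an effect. In hepatocyte-like nuclei it was 0.580 (rho 0.483) against 0.549 (0.529 to 0.578). The covariance was 0.378 against 0.162 simulated over all nuclei, a difference of 0.216, and 0.297 against 0.118 in hepatocyte-like nuclei, a difference of 0.179. With 1 control matched to each arm, r was 0.397 over all nuclei against 0.0177 (highest 0.0608) simulated, and 0.348 against 0.0107 (highest 0.0512) in hepatocyte-like nuclei. The covariance then exceeded its simulated mean by 0.368 and 0.259. With 2 controls no split keeps 2 libraries per part, and part of the excess of shared genes may come from the shared controls.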

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

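In this part, the tests of depth in the YAP 2-week library and of genes on chromosome 14 that were not called were chosen before their results were seen, and every other test of an explanation was chosen after. Genes that differed between YAP and LATS in the direct test of the 2 arms were singled out for that difference. Over all nuclei the log2 fold changes of YAP over LATS were 4.99 for Fads3, 4.01 for Tead1, 2.55 for Hells, 2.47 for Lig1 and 2.46 for Rps13-ps2, and -9.30 for Rps13-ps1, -4.35 for Abhd1, -2.80 for Gm3375, -2.35 for Gm8730 and -2.07 for Wdfy1. In hepatocyte-like nuclei they were 4.37 for Bicc1, 4.37 for Fads3, 3.71 for Tead1, 2.94 for Ifit2 and 2.52 for Csf1, and -9.37 for Rps13-ps1, -4.42 for Abhd1, -2.57 for Gm3375, -2.35 for Gm8730 and -2.05 for Wdfy1. In macrophage-like nuclei they were 7.28 for Adamdec1 and 2.59 for Rps13, and -8.25 for Rps13-ps1, -5.04 for Mup15, -4.74 for Mup16, -4.66 for Mup17 and -2.49 for Mup14, and the fitted values of Adamdec1 and Rps13-ps1 there rest on an arm without counts. The Mup values there cannot be assigned to macrophages, since hepatocyte markers summed to 29004 CPM in that class. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many genes: 32 over all nuclei, 34 in hepatocyte-like and 7 in macrophage-like nuclei, where the highest other split gave 0, 2 and 0. These splits are too few for a share under 0.05.

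The barcodes themselves gave a signal outside the comparisons. Of 62600 distinct barcodes 4046 occurred in more than 1 library, and 1061 to 3584 were shared per pair of libraries, where chance gives 5.96 if all sequences of 12 bases are equally likely. A pool of fewer barcodes used evenly for every library would raise that value for deep and shallow barcodes alike. Yet 1122 of 1142 barcodes with at least 10000 counts occurred in other libraries, 628 of them in all 8. These values argue against such a pool as the whole cause, and no test was run. Barcodes with at least 10000 counts in the library with most, at least 2 times that in any other, where found in another library, held there a median of 2.85% to 8.68% of that count, per pair of libraries.

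The first pattern is that LATS calls in hepatocyte-like nuclei include several genes near each other or of 1 family. Of the 22 calls, 5 (Cebpe, Lrit1, Lrit2, Psmb5 and Slc39a2) lie on chromosome 14 with Lats2, 2.98 to 20.6 Mb from it, which raised the idea tested here. Among genes that were not called, 10.0% of 410 on that chromosome had an unadjusted p under 0.05, against 5.83% elsewhere (Fisher's exact test over genes, one-sided p = 0.0008). Genes are not independent replicates, and the other chromosomes were pooled, so how unusual 10.0% is for 1 chromosome was not measured. Variants carried with the Lats2 locus may explain those 5 but are not shown. Calls on other chromosomes were not tested for variants, nor were calls in other classes, such as Adamdec1 on chromosome 14 in macrophage-like nuclei. Reads that only moved among Rps13, Rps13-ps1 and Rps13-ps2 would leave their sum unchanged. The log2 ratio of the summed CPM was -0.69 (473 ± 20.1 in controls, 293 ± 50.8 in LATS), which argues against such a move as the whole cause. Reads that were dropped or went to another copy would also lower the sum, so the test cannot decide on these. In YAP at 2 weeks the sum was also low, at 298 CPM, with Rps13-ps1 at 0. A response to LATS stays open and was not tested.

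The second pattern is that YAP at 2 weeks stands apart, with 88.5% of its nuclei in the unnamed cluster. Dilution of hepatocyte RNA by another cell type would lower abundant hepatocyte markers alike, but they spread over 8.13 log2 units there (Cyp2c29 to Trf), against at most 2.27 in any other library. Depth is argued against by 85.4% of the 164 shallow nuclei of that library falling in the cluster. Cholangiocyte nuclei free of hepatocyte RNA, as the whole unnamed cluster, would lower these markers by 3.12 log2 units, but 18 of 20 fell by less or rose. Nuclei of other types were not free of it. Hepatocyte markers summed to 44342 CPM in the endothelial-like and 29004 in the macrophage-like cluster, against 54137 in the unnamed one. This test therefore cannot decide on cholangiocyte nuclei, as the whole cluster or as fewer nuclei in the tissue piece. Of the cholangiocyte markers 7, among them Sox9, Spp1, Pkhd1 and Bicc1, were over 2 times the highest other library. Krt19 was at 0.619 CPM and Epcam at 2.27. A response to YAP stays open, untested, as does anything particular to that 1 library.

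The third pattern is the larger macrophage-like share in YAP libraries. Fewer recovered hepatocyte nuclei would raise endothelial-like nuclei alike. The pooled ratio of macrophage-like to endothelial-like nuclei was instead 3.33 (2.45 to 4.58) in YAP and 0.438 (0.249 to 0.745) in controls, so a change in either of these types stays open. These intervals pool nuclei and leave out the spread between libraries. By library the ratio was 1.14, 3.44 and 8.6 in YAP, the last on 5 endothelial-like nuclei, and 0.5 and 0.4 in controls. In LATS the pooled ratio was 1.53 (1.21 to 1.93), with libraries at 0.889, 1.95 and 0.786, so a ratio above controls is not particular to YAP. Depth is argued against by the lowest YAP share at 500 genes or more, 3.12% (1.62 to 5.38), above the pooled controls at 0.864% (0.504 to 1.38). A response to YAP stays open and was not tested, and the shares themselves gave an exact permutation p of 0.2.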

How the results depend on the processing

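Barcodes as first designed, no mitochondrial limit, removal of the highest 6% of doublet scores, the unnamed cluster, the settings for macrophage-like nuclei, lists over all nuclei and cycling in hepatocyte-like nuclei were chosen after the data were seen. Calls of single genes here are only those of genes that the naming rule picked, many for large and separated changes. None of these 119 calls changed direction under any setting. Under every setting run for them 10 passed, for Rps13-ps1 (4 comparisons), Gm20649, Onecut1, Amotl2, Rnaset2b, Fads3 and Gm8730. Rps13-ps1 has no value with ribosomal protein genes left out. DESeq2's size factors left every count of genes within 1.5 times. At most 5% mitochondrial counts was not run for hepatocyte-like or macrophage-like nuclei (under 20 nuclei in a library), and no endothelial-like cluster formed at resolution 0.5. Of the calls of single genes over all nuclei 21 of 52 passed by limma-voom, 17 with at most 5% mitochondrial counts, 8 without YAP 4 days, 8 without the tdTomato control and 9 without the no-dox control. In hepatocyte-like nuclei 50 of 60 passed by limma-voom, 33 with the unnamed cluster, 14 without YAP 4 days, 20 without the tdTomato control and 18 without the no-dox control. No pairing with controls was possible because they carry no time, while YAP and LATS were paired by time as a block. Where values moved, the cause was not tested, except that leaving out a library leaves fewer samples, with a lone control assumed to vary like the other groups.

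Counts of genes are given for YAP, LATS and YAP against LATS in that order. Over all nuclei (163, 4 and 32), DESeq2's Wald test gave 856, 80 and 525, no filter 1495, 247 and 1279, at most 5% mitochondrial 22, 1 and 9, and barcodes as first designed 270, 14 and 88. There limma-voom gave 20 and 2 for YAP and LATS, and for LATS no mitochondrial limit gave 12 and leaving out mitochondrial and ribosomal genes 2. In hepatocyte-like nuclei (88, 22 and 34) the Wald test gave 271, 62 and 140, no filter 533, 291 and 390, and barcodes as first designed 213, 49 and 73. No mitochondrial limit gave 134 for YAP, and the unnamed cluster gave 4 for LATS and 17 for YAP against LATS. In macrophage-like nuclei (0, 0 and 7) no filter gave 13, 22 and 60, the Wald test 2 for LATS and 11 for YAP against LATS, and for the latter limma-voom gave 0, barcodes as first designed 4, and mitochondrial and ribosomal genes left out 3. With time as a block, YAP against LATS gave 1, 17 and 38 in the 3 classes. Lists called with the estimated correlation were 0 in all 9 comparisons. With barcodes as first designed the hepatocyte-like difference was -18.2 points for YAP and also against LATS (-33.3 and -31.7), and that for LATS reversed to 0.0249, and the endothelial-like one for YAP to 0.0531 without the mitochondrial limit. Matched controls gave a covariance excess of 0.368 over all nuclei (0.216) and 0.259 in hepatocyte-like nuclei (0.179), with r of 0.397 and 0.348.

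Leaving out each library gave 0 to 634, 1 to 55 and 1 to 134 genes over all nuclei, 4 to 299, 3 to 93 and 5 to 89 in hepatocyte-like nuclei, and 0 to 3, 0 to 2 and 0 to 45 in macrophage-like nuclei. Lists called ranged from 9 to 17 for LATS and 16 to 29 for YAP against LATS over all nuclei, from 10 to 17 for YAP against LATS in hepatocyte-like nuclei, and from 1 to 14 for YAP and 3 to 11 for LATS in macrophage-like nuclei. The hepatocyte-like difference for LATS ranged from -2.54 to 0.174 points, and the endothelial-like ones from -0.489 to 0.304 for YAP, -0.408 to 0.371 for LATS and -0.514 to 0.279 for YAP against LATS. In hepatocyte-like nuclei, G2 and M-phase counts of YAP less LATS ranged from -26.1 to 648 CPM and the share of cycling nuclei from -1.97 to 6.68 points.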

Other observations

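The values here were noticed after they were seen, and no test was run on them. The 2 controls, which the comparisons average, differed in the acute-phase gene Saa1, at 2054 CPM in the tdTomato control and 70.7 in the no-dox control over all nuclei. Ankrd1 was at 0 and 4.15 CPM in the same libraries.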
